A study of Homo sapiens with 8 samples.

How the data were processed

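RNA was profiled on 8 Affymetrix Human Gene 1.0 ST arrays, with 4 arrays of A498 cells given a control siRNA and 4 given an siRNA to HIF-2alpha, all collected 48 hours after treatment. A498 is an established clear cell renal carcinoma line that lacks the VHL tumour suppressor, and the cells carried the retroviral vector pBabe, per the labels. The labels name for each array its partner in the other group, so arrays of the same number form a pair.

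The values used were the log2 expression values deposited by the authors, in a table of 28869 probe sets by 8 arrays. Affymetrix Expression Console, RMA and Partek are named in the submitters' processing notes, without versions or roles. The table gives no base of the logarithm, and log2 was taken from the range and the nearly equal quartiles of the arrays, as RMA output has. RMA corrects background, sets the arrays to a common distribution and summarises the probes of a probe set. A change in total RNA per cell would be removed by that step. Scanner files and detection calls were not used here, so no probe set could be marked as below background. The authors' genome build is not given in the sources used here, and no coordinates are reported.

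Gene symbols came from the platform annotation, in which 19310 probe sets had 1 symbol, 1752 had several and 7807 were not listed. Symbols were checked by gene number against the RefSeq genes of assembly GRCh38.p14, used for names only, and 0 symbols needed an update. Of the probe sets with 1 symbol, the brightest over all 8 arrays was kept for each gene, which left 18377 genes, 685 of them with over 1 probe set. No filter on dim genes was applied.

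Group differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, pair as a block), as log2 HIF-2alpha siRNA minus control siRNA. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The series names a paired analysis with Significance Analysis of Microarrays (SAM), whose statistic was computed here from its published definition with all 16 sign flips of the 4 pairs, as an alternative. The fit had 3 residual and 5.05 prior degrees of freedom. SE and the 95% intervals are those of the moderated fit. The number of arrays limits the precision.

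The pairing was checked from the deviations of each array from its group mean over all genes. Arrays of the same number correlated at 0.081, 0.135, 0.117 and 0.022 for pairs 1 to 4, and arrays of different number in the other group at -0.194 to 0.129, so this check alone does not separate the pairs. The block was kept because the labels name the partners and the series states a paired analysis. The labels do not say whether replicates were separate cultures or days, so the p-values measure the spread between these samples, which may be technical.

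Gene lists were written from textbook knowledge before the data were examined. The 18 lists covered HIF target genes of glycolysis, HIF target genes of the general hypoxia response, targets often assigned to HIF-2alpha, HIF pathway components, p53 targets, MYC targets, cell cycle, DNA damage checkpoint and repair, antioxidant and redox enzymes, oxidative phosphorylation, cholesterol and fatty acid synthesis, the unfolded protein and amino acid stress response, the interferon response, NF-kB and inflammatory genes, matrix and adhesion genes, renal epithelial markers, markers of other cell types and housekeeping genes. Of 440 entries, 397 were measured. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, stood beside it. After the data were seen, an exact permutation test was added, which compared each list's median with all 35 splits of the 8 arrays into 4 and 4.

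The genes named are EPAS1, HIF1A, ARNT and VHL, the 12 largest increases and 12 largest decreases among genes past the threshold that moved the same way in all 4 pairs, and up to 4 members of each list past the threshold with the largest change. Where fewer than 2 members of a list passed, the 2 with the smallest adjusted p are named by value. Symbols of uncharacterised loci and small RNAs were counted but not named. Genes named outside this rule were chosen after their values were seen, and are introduced as such.

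The fit and the list tests were first tested on simulated data for the same 18377 genes and 4 pairs. With 50 genes changed at each size, 14 were recovered at 1.25-fold, 37 at 1.5-fold, 49 at 2-fold and 50 at 3-fold, and 5 unchanged genes were called. A list shifted by 0.25 on the log2 scale was called, and 0 of 17 unshifted lists were, in data simulated without correlation between genes.

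The alternatives tried were no block, the pair as a random block, centring each array on its median, a second quantile normalization, dropping the 30% or 50% dimmest genes, the mean of all probe sets of a gene, every probe set tested, eBayes with a trended and robust prior, SAM, a paired statistic without moderation, a 1.5-fold minimum, and leaving out each pair in turn. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.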

Results

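Transcript levels were measured in A498 cells, a VHL-deficient clear cell renal carcinoma line, 48 hours after a control siRNA (4 arrays) or an siRNA to HIF-2alpha (4 arrays). VHL normally marks the HIF alpha subunits for destruction, so HIF signalling is active in such cells without hypoxia. The comparison asks which transcripts differ after the HIF-2alpha siRNA. With 1 such group, effects of the siRNA apart from the loss of HIF-2alpha cannot be told apart from the loss. Values are RMA expression on a scale taken as log2. Array medians ranged from 5.63 to 5.70, and arrays of the same group correlated at 0.996 to 0.997 over all probe sets.

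EPAS1, which encodes HIF-2alpha, was lower in the HIF-2alpha siRNA array of every pair. Its level (probe set 8041781) was 9.07 ± 0.186 with control siRNA and 7.27 ± 0.478 with HIF-2alpha siRNA (SD, n = 4 each). It fell by 1.81 on the log2 scale (SE 0.11, 95% interval -2.06 to -1.55), to 0.286 times the control level, with a limma adjusted p of 0.00148. The differences in pairs 1 to 4 were -1.83, -2.23, -1.69 and -1.48. HIF1A, the other main alpha subunit, differed by -0.26 (SE 0.0732, adjusted p 0.0678), ARNT, the shared beta subunit, by 0.17 (adjusted p 0.13) and VHL by 0.01 (adjusted p 0.947). HIF1A passed the threshold with SAM and in 6 other alternatives, among them no block (adjusted p 0.0336), the pair as a random block (0.026), the 30% dimmest genes dropped (0.0366), a trended and robust prior (0.00938) and leaving out replicate 4 (0.0423). ARNT passed with the 50% dimmest genes dropped (adjusted p 0.0403). An exact two-sided sign-flip test over 4 pairs gave p = 0.125 for EPAS1, the smallest p that 4 pairs allow.

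**Figure D1:**
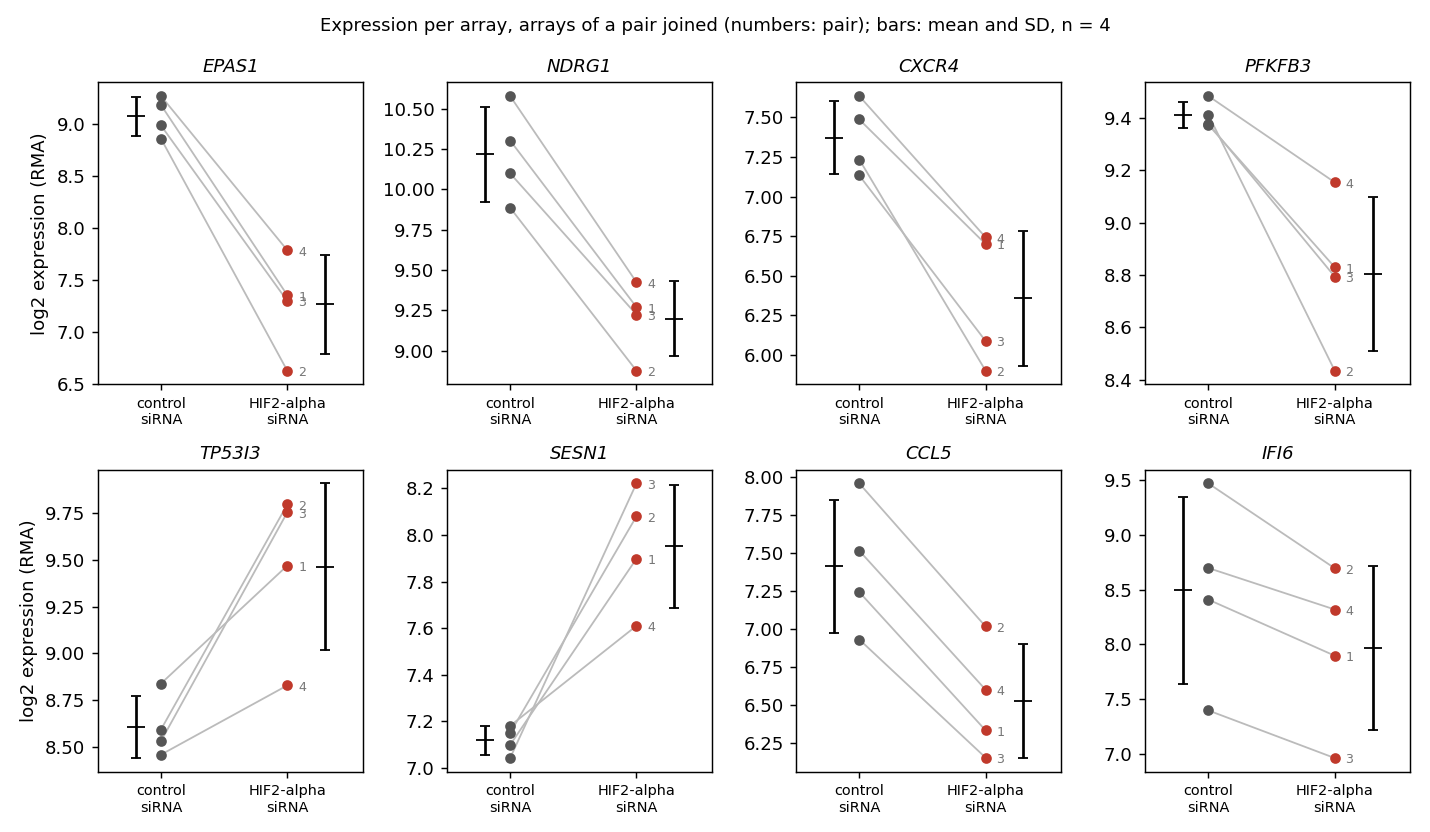
Expression per array of EPAS1, NDRG1, CXCR4, PFKFB3, TP53I3, SESN1, CCL5 and IFI6 (y axis, log2 RMA units, not starting at 0; x axis, siRNA), with the arrays of a pair joined and numbered, and bars for the mean and SD of 4 arrays. EPAS1 fell from 9.07 to 7.27 on average, and for IFI6 the arrays of a group spread more widely (SD 0.856 with control siRNA) than the mean change of -0.52.

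Across 18377 genes, 613 were higher and 869 lower after HIF-2alpha siRNA, and each of these moved the same way in all 4 pairs. The paired fit that selected these genes used the same differences and favours such agreement, so the agreement is no separate support. Apart from EPAS1, the largest decreases were in MAP7D2 (-1.23), a microtubule-associated protein, EIF4EBP2 (-1.18), a repressor of cap-dependent translation, CYB5R2 (-1.18), a cytochrome b5 reductase, CD24 (-1.10), a surface glycoprotein, PTBP3 (-1.05), an RNA-binding protein, RNASET2 (-1.05), a ribonuclease, LIPA (-1.04), the lysosomal acid lipase, NDRG1 (-1.02), a hypoxia-inducible gene, CXCR4 (-1.01), a chemokine receptor, ITPR1 (-1.0), a calcium channel of the endoplasmic reticulum, and PKIA (-1.0), an inhibitor of protein kinase A. SE ranged from 0.064 for NDRG1 to 0.211 for CD24. The largest increases were in the noncoding RNA LINC01951 (1.16), ANKRD1 (1.10), NTN4 (1.05), a basement membrane netrin, PRDM1 (1.03), a transcriptional repressor, STX12 (0.90), DCP2 (0.88), an mRNA decapping enzyme, TIGAR (0.86), TP53I3 (0.86), SESN1 (0.83), ABCA12 (0.82), a lipid transporter, EXPH5 (0.79) and SFN (0.75). Changes were mostly small, with 39 higher and 109 lower genes at 1.5-fold or more, and 4 higher and 10 lower at 2-fold or more.

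Without replicate 1, 2 or 3, the counts were 42, 42 and 34 higher and 140, 128 and 100 lower, and without replicate 4 they were 612 and 849. LINC01951 varied between arrays of a group (SD 0.753 with control siRNA) and did not pass without the pair as a block (adjusted p 0.154). CD24 missed the threshold when every probe set was tested (adjusted p 0.0541) and without replicate 1 (0.0748) or 3 (0.093). Among the largest increases, STX12, TP53I3 and ABCA12 each missed it without replicate 1, 2 or 3 (adjusted p 0.0532 to 0.067).

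**Figure D2:**
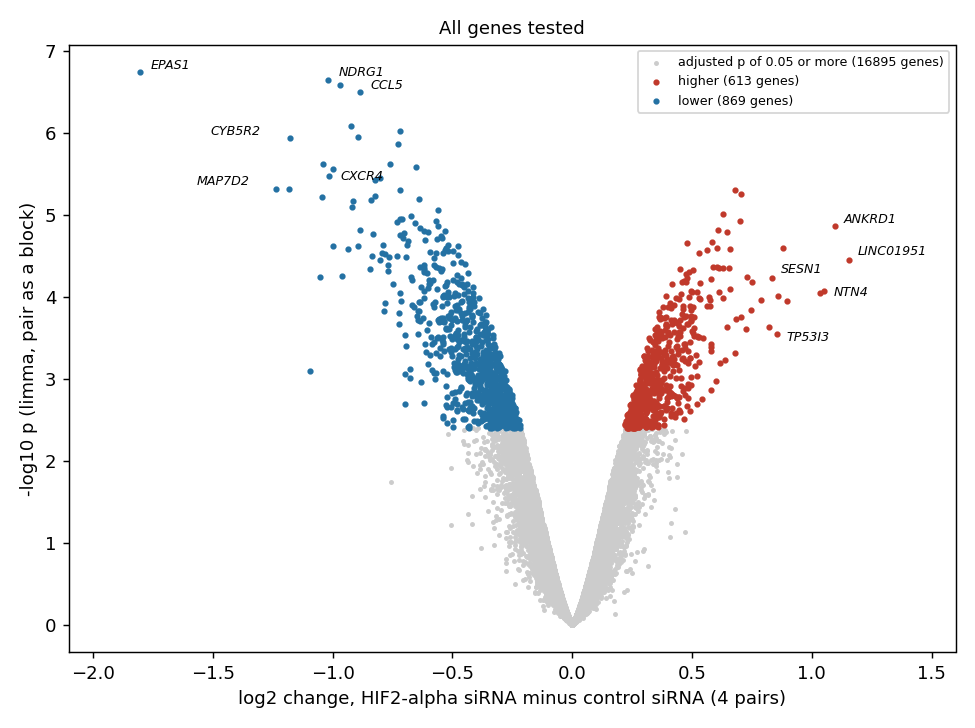
Log2 change (x axis, HIF-2alpha siRNA minus control siRNA, mean of 4 pairs) against -log10 of the limma p (y axis) for 18377 genes, each point a gene. The 869 lower genes reach further from 0 (EPAS1 at -1.81) than the 613 higher genes (LINC01951 at 1.16).

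More known HIF targets fell than rose after HIF-2alpha siRNA in each of the 3 target lists. Of 20 targets often assigned to HIF-2alpha, 8 fell and 0 rose (9 fell when adjusted over the list alone), led by CXCR4 (-1.01), ITPR1 (-1.0), IGFBP3 (-0.97), an insulin-like growth factor binding protein, and PLIN2 (-0.72), a lipid droplet coat protein. VEGFA, named after its value was seen, fell by 0.70 (SE 0.0773). The list was lower than other genes with camera (adjusted p 4.67e-06), with adjusted p = 0.136 with an estimated correlation and 0.0112 with fry. Its median of -0.126 was larger in size than in any other of the 35 splits of the arrays (exact permutation p 0.0286, the smallest possible, adjusted over the lists 0.129). By pair the median was -0.203, -0.027, -0.307 and -0.233 for pairs 1 to 4. It was thus smallest in size in pair 2, where EPAS1 fell most (-2.23).

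Of 21 glycolytic HIF targets, 7 fell and 0 rose (11 fell and 1 rose when adjusted over the list alone). PFKFB3, a regulator of glycolytic flux, fell by 0.61 (SE 0.0983), the enolase ENO2 by 0.57 (SE 0.0826), the glucose transporter SLC2A3 by 0.51 (SE 0.0788) and the aldolase ALDOC by 0.31 (SE 0.0663). ALDOC missed the threshold when every probe set was tested (adjusted p 0.0651). The list gave a camera adjusted p of 1.95e-05, with adjusted p = 0.136 with an estimated correlation and 0.0112 with fry, and its median of -0.175 exceeded all other splits (exact permutation p 0.0286, adjusted 0.129). Without replicate 1, 2 or 3, the members that fell numbered 0, 1 and 0.

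Of 29 general hypoxia targets, 8 fell and 2 rose (9 and 3 when adjusted over the list alone). NDRG1 fell by 1.02 (SE 0.064), BNIP3L, a mitophagy receptor, by 0.73 (SE 0.0577), EGLN3, a HIF prolyl hydroxylase, by 0.65 (SE 0.0563) and ADM, the peptide adrenomedullin, by 0.56 (SE 0.06). INSIG2 (0.45), which retains sterol sensors in the endoplasmic reticulum, and TMEM45A (0.31), a transmembrane protein, were the members that rose, and are named after their values were seen. The camera adjusted p was 0.00197, with adjusted p = 0.428 with an estimated correlation and 0.0164 with fry. The median of -0.078 was matched or exceeded in 4 of the 35 splits (exact permutation p 0.114) and in none of the other splits that part every pair (largest 0.074). Without replicate 1, 2 or 3, the members that fell numbered 5, 5 and 5. Among 13 HIF pathway components, EPAS1 alone passed (2 fell when adjusted over the list alone), and the list did not pass the test against other genes (camera adjusted p 0.152).

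Of 31 targets of p53, the tumour suppressor that controls cell cycle arrest and death after stress, 13 rose, 0 fell and 18 did not pass (18 rose when adjusted over the list alone). The list was higher than other genes with camera (adjusted p 1.9e-11), with adjusted p = 0.428 with an estimated correlation and 0.059 with fry. TIGAR, a brake on glycolysis, rose by 0.86 (SE 0.121), TP53I3, a quinone reductase, by 0.86 (SE 0.14), SESN1, a stress-induced sestrin, by 0.83 (SE 0.109) and PPM1D, a phosphatase that dampens p53 signalling, by 0.73 (SE 0.095). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, differed by -0.06 (95% interval -0.199 to 0.087), and MDM2, the ubiquitin ligase for p53, rose by 0.26 (SE 0.0559). Both of these are named after their values were seen. The median change of the list was 0.26, and by pair it was 0.237, 0.315, 0.341 and 0.097 for pairs 1 to 4.

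The estimated correlation between the p53 targets was 0.557. Their median exceeded that of all other splits of the arrays (exact permutation p 0.0286, adjusted 0.129), the largest other being 0.219. Without replicate 1, 2 or 3, the members that rose numbered 3, 3 and 3, and without replicate 4 they numbered 17.

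Of 23 interferon response genes measured, 10 fell and 0 rose (11 fell when adjusted over the list alone). The chemokine CCL5 fell by 0.89 (SE 0.0582), and the interferon-induced IFI44L by 0.72 (SE 0.114), IFI6 by 0.52 (SE 0.0757) and IFIT2 by 0.37 (SE 0.0697). Levels of these genes also differed between pairs, as for IFI6 at 8.49 ± 0.856 with control siRNA and 7.97 ± 0.745 with HIF-2alpha siRNA (SD, n = 4 each). The camera adjusted p of the list was 9.04e-08, with adjusted p = 0.428 with an estimated correlation and 0.059 with fry. Without the pair as a block, 1 of the 10 members passed, and the adjusted p was 0.0557 for IFI44L, 0.514 for IFI6 and 0.293 for IFIT2. IFIT2 also missed the threshold when every probe set was tested (adjusted p 0.0502). Without replicate 1, 2 or 3, the members that fell numbered 1, 2 and 1. In 15 of the 35 splits the list's median was as large as the -0.211 observed (exact permutation p 0.429), and other splits reached 0.51, but among the 8 splits that part every pair the largest other was 0.15.

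Of 19 NF-kB and inflammatory genes, the chemokine CCL2 (-0.44, SE 0.0829) and the cytokine IL6 (-0.35, SE 0.0625) fell and 0 rose (4 fell and 2 rose when adjusted over the list alone). The list did not pass the test against other genes (camera adjusted p 0.661), and without the pair as a block CCL2 (adjusted p 0.061) and IL6 (adjusted p 0.186) missed the threshold. CCL2 also missed it when every probe set was tested (adjusted p 0.0511), and both CCL2 and IL6 missed it without replicate 1, 2 or 3 (0.067 to 0.0922).

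Of 29 antioxidant and redox enzymes, 4 fell and 3 rose (4 and 5 when adjusted over the list alone). The heme oxygenase HMOX1 fell by 0.84 (SE 0.0816), GPX8 by 0.49 (SE 0.0915, missing the threshold at adjusted p 0.0504 when every probe set was tested) and the mitochondrial peroxiredoxin PRDX3 by 0.37 (SE 0.0663), while the malic enzyme ME1 rose by 0.42 (SE 0.0658). GPX8, PRDX3 and ME1 each missed the threshold without replicate 1, 2 or 3 (limma adjusted p 0.0557 to 0.0849). The list as a whole did not pass (camera adjusted p 0.175). Of 27 oxidative phosphorylation genes, TFAM, which maintains mitochondrial DNA, fell by 0.48 (SE 0.0826) and 0 rose (1 fell when adjusted over the list alone). TFAM missed the threshold without replicate 1, 2 or 3 (limma adjusted p 0.0723 to 0.0776). In the list, 22 members had a positive and 5 a negative difference. The list median was 0.084 (camera adjusted p 0.0768, and 0.0323 without replicate 2), larger than in any other of the 35 splits (exact permutation p 0.0286, adjusted 0.129, largest other 0.069). SDHC, read from the brighter of its 2 probe sets, differed by -0.20 (adjusted p 0.0626). It passed with SAM, with the 30% (0.0305) or 50% (0.0143) dimmest genes dropped and with a trended and robust prior (0.0139).

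Of 21 genes of cholesterol and fatty acid synthesis, MSMO1 (-0.43, SE 0.0775), a sterol oxidase, and ACLY (-0.31, SE 0.0662), which makes cytosolic acetyl-CoA, fell and 0 rose (9 fell when adjusted over the list alone). The camera adjusted p was 0.0127, with adjusted p = 0.462 with an estimated correlation and 0.0931 with fry. It was 0.066 without the pair as a block and 0.0808 without replicate 3, and 13 of the 35 splits gave a median as large as -0.122 (exact permutation p 0.371), but none of the other splits that part every pair did (largest 0.09). The median was 0.017 in pair 1 and -0.139, -0.187 and -0.085 in pairs 2 to 4, and it was -0.063 without replicate 2. MSMO1 missed the threshold without the block (adjusted p 0.159), ACLY when every probe set was tested (adjusted p 0.066), and without replicate 1, 2 or 3 the members that fell numbered 1, 0 and 0.

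None of the 4 lists of proliferation and stress genes passed the test against other genes. Of 32 cell cycle genes, RRM2, a subunit of ribonucleotide reductase, fell by 0.33 (SE 0.0772) and the replication helicase subunit MCM5 by 0.24 (SE 0.0603), and 0 rose (0 passed when adjusted over the list alone, camera adjusted p 0.589). MCM5 missed the threshold with arrays centred on their medians (adjusted p 0.0518), and both MCM5 (0.092) and RRM2 (0.0806) missed it when every probe set was tested. Of 23 MYC targets, NOLC1, a nucleolar protein, rose by 0.66 (SE 0.0828) and 0 fell (1 rose when adjusted over the list alone), with a camera adjusted p of 0.422. MYC differed by -0.22 (adjusted p 0.0658), and passed with SAM, without the pair as a block (0.0412), with it as a random block (0.0302), with the 30% (0.0339) or 50% (0.0169) dimmest genes dropped and with a trended and robust prior (0.00991).

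Of 20 genes of DNA damage checkpoint and repair, 0 passed with limma or SAM over all genes or over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p 0.785). BRCA1 differed by -0.21 (adjusted p 0.0835) and XRCC1 by 0.18 (adjusted p 0.118), and both passed with the 50% dimmest genes dropped (0.0238 and 0.0365). BRCA1 also passed with the 30% dimmest dropped (0.0447) and with a trended and robust prior (0.0283). Of 21 genes of the unfolded protein and amino acid stress response, 0 passed with limma or SAM over all genes or over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p 0.992). SDF2L1 differed by 0.22 (adjusted p 0.0893, and 0.049 with the 30% and 0.0266 with the 50% dimmest genes dropped, and 0.0483 with a trended and robust prior) and XBP1 by -0.14 (adjusted p 0.174).

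Of 28 matrix, adhesion and mesenchymal genes, 3 rose and 3 fell over all genes and over the list alone (camera adjusted p 0.422). The matrix protein TGFBI fell by 0.69 (SE 0.078), while CCN1 rose by 0.49 (SE 0.0833), THBS1, thrombospondin, by 0.45 (SE 0.0631) and CCN2 by 0.39 (SE 0.08). CCN2 missed the threshold when every probe set was tested (adjusted p 0.0609). CCN1, THBS1 and CCN2 each missed it without replicate 1, 2 or 3 (adjusted p 0.052 to 0.107). Of 17 renal epithelial markers, the cadherin CDH6 (-0.62, SE 0.138) and the membrane peptidase MME (-0.53, SE 0.0843) fell and 0 rose (3 fell when adjusted over the list alone, camera adjusted p 0.133). CDH6 missed the threshold when every probe set was tested (adjusted p 0.0754), and both CDH6 and MME missed it without replicate 1, 2 or 3 (0.0597 to 0.131).

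Of 14 markers of blood, endothelium and muscle, LYZ rose by 0.25 from a level of 2.89 ± 0.191 (SD, n = 4, adjusted p 0.0401, but 0.153 without the pair as a block and 0.0797 when every probe set was tested), near the low end of the arrays, and 0 fell (1 rose when adjusted over the list alone, camera adjusted p 0.422). CD3D differed by 0.21 from a level of 3.30 (adjusted p 0.214). Of 9 housekeeping genes, 0 passed with limma or SAM over all genes or over the list alone, and 1 had an unadjusted p under 0.05. GUSB differed by -0.13 (adjusted p 0.209) and B2M by 0.09 (adjusted p 0.412). The list's median was -0.005 and its mean 0.001, and camera (down, adjusted p 0.992) and fry (up, adjusted p 0.967) differed in sign.

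In all, 6 of 18 lists passed with camera at the preset correlation, 0 with an estimated correlation and 3 with fry (the 3 lists of HIF targets). After adjustment over the 18 lists, the exact permutation test gave 0.129 at the lowest. Its smallest possible p before adjustment is 0.0286, so an adjusted p under 0.05 would need most of the 18 lists at that value. The adjusted result therefore decides little for any single list. The permutation test treats the 8 arrays as independent, and the 8 splits that part every pair are too few for a p under 0.05.

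**Figure D3:**
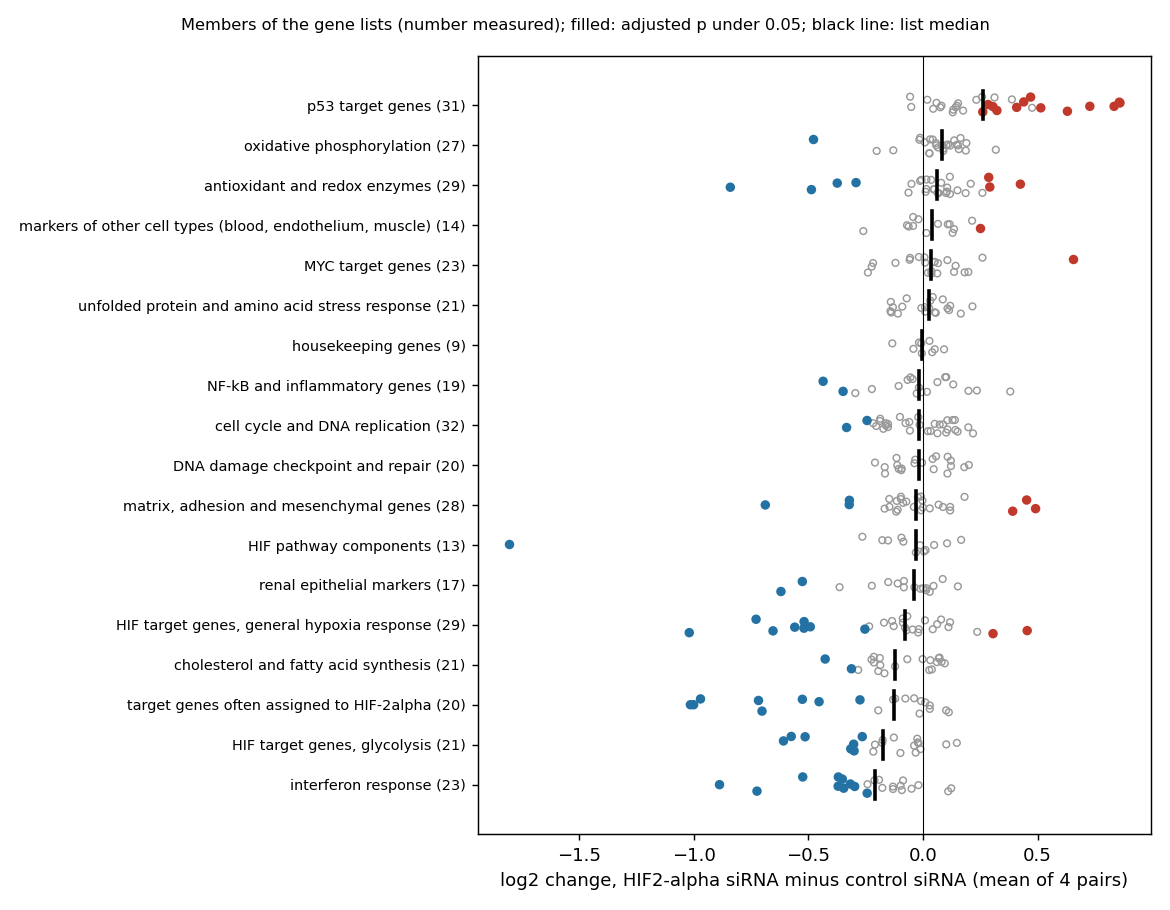
Log2 change (x axis, HIF-2alpha siRNA minus control siRNA, mean of 4 pairs) of each measured member of the 18 gene lists (y axis, number measured in brackets), with filled points for adjusted p under 0.05 and black lines for list medians. The p53 targets have the highest median (0.26) and the interferon response the lowest (-0.211).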

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

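The spread within each group of 4 arrays was examined for the 69 named genes and the array median, 140 groups in all, by the gap of the most distant array to its nearest neighbour as a share of the group's range. Dixon's critical value at the 95% level was passed by 8 groups, and chance gives about 1 in 20, or 7 groups.

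Among control siRNA arrays, EGLN3 was low in replicate 2 (8.59 against 8.84 to 8.88, share 0.870), HMOX1 low in replicate 4 (10.2 against 10.4, share 0.932) and CCN1 low in replicate 3 (8.39 against 8.71 to 8.75, share 0.872). PRDX3 was high in replicate 4 (11.2 against 11.1, share 0.854) and TGFBI high in replicate 1 (11.7 against 11.6, share 0.868). After HIF-2alpha siRNA, GUSB was low in replicate 3 (8.39 against 8.65 to 8.69, share 0.882).

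The median of the array was low in control siRNA replicate 3 (5.63 against 5.67 to 5.68, share 0.881) and high in HIF-2alpha siRNA replicate 2 (5.70 against 5.65 to 5.66, share 0.848). No array had more than 2 of the 8 flags.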

How the results depend on the processing

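The alternatives were chosen before the data were examined. EPAS1 was lower under all of them (-1.91 to -1.66 with each pair left out) and stayed past the threshold except with the paired statistic without moderation (-1.81, adjusted p 0.156). That statistic has 3 degrees of freedom per gene and called 1 higher gene (ADORA2B, named after its value was seen) and 0 lower, with 1768 higher and 1782 lower at an unadjusted p under 0.05. SAM called 766 and 1275, and these held all 1482 genes of the paired limma fit.

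Higher genes numbered 1115 with the 50% dimmest genes dropped, 1133 with a trended and robust prior, 39 at 1.5-fold or more and 34 to 612 with each pair left out. Lower genes numbered 109 at 1.5-fold or more and 100 to 849 with each pair left out. With every probe set tested, 254 probe sets were higher and 441 lower, 79 of these 695 without a single symbol, and 588 of the 1482 genes remained. That test brings in 9559 probe sets without a single symbol. Leaving out a pair leaves fewer samples, but why replicate 4 mattered less than the others was not tested. Pair 4 had the smallest fall of EPAS1 (-1.48 against -1.69 to -2.23). Its median was also the smallest for p53 targets (0.097 against 0.237 to 0.341). For general hypoxia targets its median was instead the largest in size (-0.123 against -0.038 to -0.062). Without the replicate block, 677 were higher and 823 lower, and 1251 of the 1482 genes remained. The genes past the threshold had the same sign under every alternative in which they were tested. Only centring, a second quantile normalization and the mean of all probe sets could have turned a sign. The other alternatives used the same mean difference, or left out a pair when each gene had moved the same way in all 4 pairs.

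With an estimated correlation the adjusted p was 0.136 for glycolysis and for HIF-2alpha targets. It was 0.428 for general hypoxia, p53 and interferon, and 0.462 for cholesterol and fatty acid synthesis. For glycolysis (-0.028) and HIF-2alpha targets (-0.001) the estimated correlation lay under the preset 0.01. For those lists this argues against a higher correlation between genes as the cause of the higher adjusted p. The estimate lay above the preset for general hypoxia (0.044), p53 (0.557), interferon (0.342) and cholesterol and fatty acid synthesis (0.169). With fry the adjusted p was 0.059 for p53 and for interferon and 0.0931 for cholesterol and fatty acid synthesis. The last list also missed without the block (0.066) and ranged from 0.00188 to 0.0808 with each pair left out. Other causes were not tested. The other 5 called lists passed without the block and with each pair left out.

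Directions turned only where nothing had passed. VHL ranged from -0.042 to 0.057 with each pair left out. List directions turned for housekeeping genes (adjusted p 0.967 with fry, 0.966 without the block, 0.942 with the 30% dimmest genes dropped, 0.793 to 0.979 with a pair left out), the unfolded protein response (0.966 without the block, 0.705 to 0.979), cell cycle (0.311 to 0.919), DNA repair (0.522 to 0.919) and markers of other cell types (0.925 with the 30% dimmest genes dropped).

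Of the 68 named genes other than EPAS1, 8 lost their call without the block, 11 with every probe set tested, and 27, 26, 30 and 2 without replicate 1, 2, 3 and 4. Without signal over background, dim genes such as LYZ cannot be marked as detected: of genes ranked by mean expression, 68 of the dimmest 4595 passed, against 694 of the brightest 4594.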

Other observations

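The test of similar brightness, the question of a different siRNA and the iron handling list were chosen after the results they bear on were seen, as were the added gene lists themselves. Other p53 targets were written as a further list without having seen their values. Of 52 measured, 16 rose, 0 fell and 36 did not pass (21 rose when adjusted over the list alone). Those that rose included POLH, a translesion polymerase (0.61, SE 0.0773), CYFIP2 (0.53, SE 0.0983), ANKRA2 (0.53, SE 0.0878), FBXO22 (0.51, SE 0.0641) and ASCC3 (0.47, SE 0.0621). These members are named after their values were seen. Their median of 0.162 lay above all 10000 random lists matched on mean expression (percentile 100), and camera gave an adjusted p of 1.13e-10, with adjusted p = 0.413 with an estimated correlation. A rise limited to the members first chosen is thus argued against for these arrays. Both lists were read on the same 8 arrays, so the second is no independent test of a p53 response.

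For the rise of p53 targets, a single decisive pair is argued against, since the median stayed at 0.217 or more whichever pair was left out, against 0.13 for a fall to 0.5 of its value. A shift shared by genes of similar brightness is also argued against, since the median lay at percentile 100 of matched random lists. An effect of the siRNA apart from the loss of EPAS1 cannot be told apart from the loss itself, because only 1 group received an siRNA to EPAS1. That limit holds for every change reported here. A change in p53 activity with less HIF-2alpha may be a biological explanation, and it stays open and untested.

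For the fall of interferon response genes, similar brightness is argued against, since the median lay below all matched random lists (percentile 0). The list median was -0.242, -0.402, -0.111 and -0.191 in pairs 1 to 4, so the direction does not rest on 1 pair. Whether 1 pair decides the size of the fall stays open. Without the pair that moves it most the median was -0.158. That is beyond the -0.106 that marks 0.5 of its value, but by less than the spread of 0.055 over members. A response set off by the control siRNA itself could give the same difference and cannot be told apart here, because there were 0 arrays of untransfected cells. A biological effect of lower HIF-2alpha on interferon signalling also stays open and untested.

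Other groupings of the 8 arrays were fitted in the same way. With the groups as independent samples, 1 of the 35 splits, the real one, called as many as 1500 genes and the highest other called 0, which excludes chance only if the arrays of a pair are independent. With the pair as a block, the real split called 1482 genes and the highest other of 8 called 0, and 8 splits are too few for a share under 0.05. For the count of lists chance cannot be excluded even then: as independent samples the real split called 5 lists, 13 of the 35 splits called as many and the highest other called 8. With the pair as a block, 2 of 8 splits called as many as the real 6, the highest other also being 6, and 8 splits are too few for a share under 0.05.

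Hypotheses about wider groups were tested on further lists that left out the genes that prompted them. ANKRD1, CCN1 and CCN2, targets of the YAP and TEAD factors, rose, which may reflect a rise of that group. Of 20 other such targets 4 rose and 4 fell, over all genes and over the list alone, and the median of 0.049 lay at percentile 80.45, which leaves this open because members went both ways. LIPA and RNASET2, both lysosomal, fell, and the median of 25 other lysosomal genes was -0.045 (percentile 3.42), but 2 rose and 1 fell and the difference from the bound was within the spread of 0.025, so a fall of the group also stays open. HMOX1 and CP, named after its value was seen (-0.67, SE 0.0694), fell, while 14 other iron handling genes had a median of 0.033 (percentile 71.11) with 0 rising and 1 falling, SLC11A2 (-0.28, SE 0.065), named after its value was seen. The median of these 14 genes did not fall. It lay above the bound of -0.039 from matched random lists by more than the spread of 0.026 over members. Members went both ways, and some lay near the low end of the arrays. A fall of the group thus stays open, as for the YAP and TEAD targets. One such dim gene was HEPH (3.02 with control siRNA), named after its value was seen. Camera gave an adjusted p of 0.567 for each of these 3 lists.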
